A study of Bos taurus with 37 samples.

How the data were processed

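The data were 37 one-colour (Cy3) Agilent bovine arrays of total RNA from peripheral blood mononuclear cells. In the infusion study, 24 arrays held the same 4 cows under Na2EDTA and under CaEDTA at 0, 4 and 24 h, and 13 arrays held 4 cows with milk fever that recovered after a single treatment (A), 4 that needed further treatment (B) and 5 healthy cows (H). Groups were taken from the deposited labels, and cows are named by the replicate numbers of the titles.

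The authors scanned the arrays and extracted spots with Agilent Feature Extraction 9.5, per the submitters' processing notes. The scanner files give each spot's processed signal in units of intensity, per the file headers, after the software's spatial and multiplicative detrending. The deposited value table is in log2 units: on each array it was the log2 of the processed signal minus a constant, to within 3.44e-06, with medians of -3.58 to -3.11. The processed signal of the scanner files was used here, spots of the same probe were averaged, and each array was scaled to its 75th percentile on the log2 scale. That percentile lay between 803 and 3091 intensity units. Between 51.7% and 82.6% of 15208 probes were well above background, by the flag that Feature Extraction gives. The number of arrays, not a depth, limits the precision.

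A gene symbol was given to 7051 of 15208 probes, which stand for 6719 genes, through the RefSeq table for assembly ARS-UCD2.0: 2496 by accession, 1986 by gene number, 1280 by symbol, 985 by description and 304 by synonym. Another 8155 probes stayed unnamed and 2 matched several genes, and 226 genes had more than 1 probe.

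Probes were tested when well above background on at least 3 arrays of at least 1 group of the fit, which left 10305 probes in the infusion study and 12190 in the milk fever study. Linear models were fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with statmod 1.5.0. The infusion study used 1 fit of 6 groups with the cow (replicate number) as a fixed block, and the milk fever study 1 fit of 3 groups with no block. Adjusted p are Benjamini-Hochberg values within a comparison, and a probe was called at an adjusted p under 0.05. There were 9 comparisons in the infusion study, 2 of them tests of the difference between the infusions in a change over time, and 4 in the milk fever study. These models, the filter, the gene lists, the rule for naming genes and the alternatives were fixed before the data were examined, apart from those said to be chosen later. Each comparison is reported by the count of called probes and by genes named by the following rule. Up to 10 of the genes with the largest rise and up to 10 of those with the largest fall among called probes with a symbol are named, each by its probe of highest mean signal, and another probe of the gene that was not called or was called the other way is mentioned. From a called list up to 4 members of smallest p are named, where fewer than 3 genes pass the 5 of smallest p, and for overlaps up to 10 genes.

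That the numbers pair the cows rests on the series design text, and was checked on residuals after group means were removed. Arrays of a cow at 0 and 4 h of the same infusion correlated at 0.20 to 0.72, but each such pair shared a slide, which can raise the correlation by itself. Pairs of the same infusion with a 24 h array, on another slide, correlated at -0.07 to 0.58. Arrays of a cow under the other infusion at 0 or 4 h lay on the other slide and correlated at -0.47 to 0.12, and at 0.13 to 0.69 in 8 such pairs once slide means were removed. With 2 arrays of a group on a slide, these 8 values compare only cow 1 with cow 4 and cow 2 with cow 3. They are thus not independent and cannot check the pairing between these sets of cows. No pair of arrays was identical, and the highest correlation between any 2 was 0.990.

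Lists of genes for 32 cell types and pathways were tested with camera at a preset inter-gene correlation of 0.01 on 1 probe per gene, for lists with at least 3 tested members, with Benjamini-Hochberg adjustment over the lists of a comparison. Camera with an estimated correlation and fry were run beside it. A list's shift is the median log2 difference of its members. The overlap of called probes was compared with the product of list sizes, with Fisher's exact test where no array was shared, and with simulated groups where healthy arrays were shared. Other splits of the arrays into groups of the same sizes were refitted, at most 100 per comparison.

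Alternatives were normexp background correction with an offset of 50, quantile normalization, median centring, no filter on dim probes, a filter on every array, the deposited value table, an intensity trend, array weights, an added limit of 1 on the log2 change, no block, the slide as a term or a block, single slides, fits of fewer or more groups, and each cow or array left out. On simulated data with log2 changes of 1, 2 and 3 added to randomly chosen probes, the fit recovered 50.7%, 88.1% and 90.9% for Na2EDTA against CaEDTA at 4 h and 29.9%, 76.1% and 89.4% for group A against group H. No array was left out. Tables were read with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.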

Results

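Gene expression in peripheral blood mononuclear cells (PBMC, the lymphocytes and monocytes of the blood) of Holstein cows was measured on 37 one-colour Agilent arrays. Each array held 15208 probes other than controls. In the infusion study, 24 arrays came from a crossover of 4 cows. Each cow received Na2EDTA, a chelator that binds calcium in the blood, and CaEDTA, which already carries calcium and served as the control. Cells were taken before the infusion (0 h), at its end (4 h) and at 24 h, which gave 6 groups of 4 arrays. The other 13 arrays came from cows around calving: 4 with milk fever (hypocalcaemia at calving) that stood after a single calcium treatment (group A), 4 with milk fever that needed more treatment (group B), and 5 healthy cows (group H). Between 51.7% and 82.6% of the probes of an array were well above background. That share was 58.3% to 71.2% in group A, 72.9% to 77.2% in group B and 78.9% to 82.6% in group H. The mean net signal of the negative controls was 39.6 to 60.7 intensity units in group A, 36.3 to 41.9 in group B and 20.3 to 22.6 in group H. Differences of dim genes from group H can thus include one of background. The 0 h and 4 h arrays lay on slides 1 and 2, each with 2 arrays of each of their 4 groups. Slide 1 held Na2EDTA arrays of cows 2 and 3 and CaEDTA arrays of cows 1 and 4, and slide 2 the reverse. A comparison of the infusions within a slide is thus between different cows and is not paired. All 24 h arrays lay on slide 3, and groups A, B and H had a slide each. The number of arrays limits the precision. Changes below are log2 differences ± SE of the fit (limma), over 4 cows in the infusion study. A gene or probe counts as changed at an adjusted p under 0.05. Gene lists were tested with camera, and the p that follows each list's p is the same test's adjusted p with an estimated correlation. None of the 79 list calls passed with it, and the test fry called 15 lists, 12 of them among the 79.

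The comparison of Na2EDTA with CaEDTA at 4 h asked how the cells differed at the end of induced hypocalcaemia. RAB26, a small GTPase of vesicle transport, was 4.5-fold higher in Na2EDTA (log2 difference 2.17 ± 0.35, adjusted p = 0.0239) and SLC49A4, a membrane transporter, 3.9-fold higher (1.96 ± 0.34, adjusted p = 0.0272). BIRC3, an inhibitor of apoptosis in NF-kB signalling, was lower (-0.94 ± 0.16, adjusted p = 0.0239). Each of these 3 genes differed in the stated direction in 4 of 4 cows. They were the named genes among 10 probes that differed, 8 higher and 2 lower. Among the unnamed probes, chosen after their values were seen, ABR5229 had the largest difference (2.61 ± 0.37, adjusted p = 0.00791) and ABR4281 the lowest adjusted p (1.87 ± 0.23, adjusted p = 0.00222).

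At 4 h, 5 gene lists were higher and 4 lower in Na2EDTA than in CaEDTA, although no member of these 9 lists passed over all probes. The neutrophil list, granule and receptor genes of neutrophils, had a median difference of 1.27 with 13 of 14 members higher (adjusted p = 1.33e-05, and adjusted p = 0.176 with an estimated correlation). Adjusted over the list alone, 2 of its members passed, the antimicrobial protein BPI (4.06 ± 0.81, adjusted p = 0.0649 over all probes) and the cathelicidin CATHL1 (at least 1.81-fold, adjusted p = 0.383 over all probes). Such a bound is given where no array of the lower group was well above background, and takes the dimmest signal well above background on each array as that group's value. With 2 members at their bounds the median of the neutrophil list was 0.92, a check chosen after seeing the data. The glucocorticoid response list had a median of 0.63 (adjusted p = 0.00157, and 0.176 as the adjusted p with an estimated correlation). Of its 13 members, 4 passed adjusted over the list alone: CXCR4, a chemokine receptor (1.90 ± 0.55), ZBTB16, a transcription factor induced by glucocorticoids (1.45 ± 0.41), GLUL, glutamine synthetase (1.42 ± 0.42), and IL1R2, a decoy receptor for interleukin 1 (2.51 ± 0.92). The monocyte list (0.49, 16 of 17 higher, CD14 1.57 ± 0.57, adjusted p = 0.00157), the hypoxia and glycolysis list (0.32, LDHA 0.44 ± 0.27, adjusted p = 0.00157) and the natural killer (NK) and cytotoxic cell list (0.61, GNLY 1.01 ± 0.40, adjusted p = 0.0194) were higher too. With an estimated correlation their adjusted p were 0.43, 0.176 and 0.449.

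Of the lists lower in Na2EDTA at 4 h, B cell genes had a median of -0.43 with 7 of 7 members lower (CD79A of the B cell receptor -0.49 ± 0.24, adjusted p = 0.00301) and T cell genes one of -0.27 (CD3G -0.56 ± 0.36, adjusted p = 0.0314). Cholesterol synthesis genes had a median of -0.27 (CYP51A1 -0.90 ± 0.32, HMGCS1 -0.76 ± 0.28, adjusted p = 0.00157) and calcium transport and sensing genes one of -0.20 (the channel TRPV2 -0.60 ± 0.22, adjusted p = 0.00797). With an estimated correlation the adjusted p was 0.176 for the B cell, cholesterol and calcium lists and 0.479 for the T cell list. Within a slide the infusions came from different cows, so its medians mix cow with infusion. Within slides 1 and 2, in this order, the medians were 0.95 and 1.33 for neutrophil, 0.51 and 0.74 for glucocorticoid, 0.31 and 0.61 for monocyte, 0.20 and 0.40 for hypoxia and -0.01 and 1.18 for NK genes. They were -0.55 and -0.35 for B cell, -0.30 and -0.43 for T cell, -0.24 and -0.30 for cholesterol and -0.26 and -0.13 for calcium genes. As probe counts, the slide as a further term gave 32 calls, the slide as a block in place of the cow 8 (8 higher, 0 lower), and slides 1 and 2 by themselves 2 and 1. Without the cow block 3 probes were called, in a fit of the 4 h groups alone 0, with normexp 6, and with no filter 2. Array weights gave 4733 (2275 higher, 2458 lower), quantile normalization 12 and median centring 8 (none lower in either). Without cow 1, 2 or 3 the count was 1 each, and without cow 4 it was 4.

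**Figure D1:**
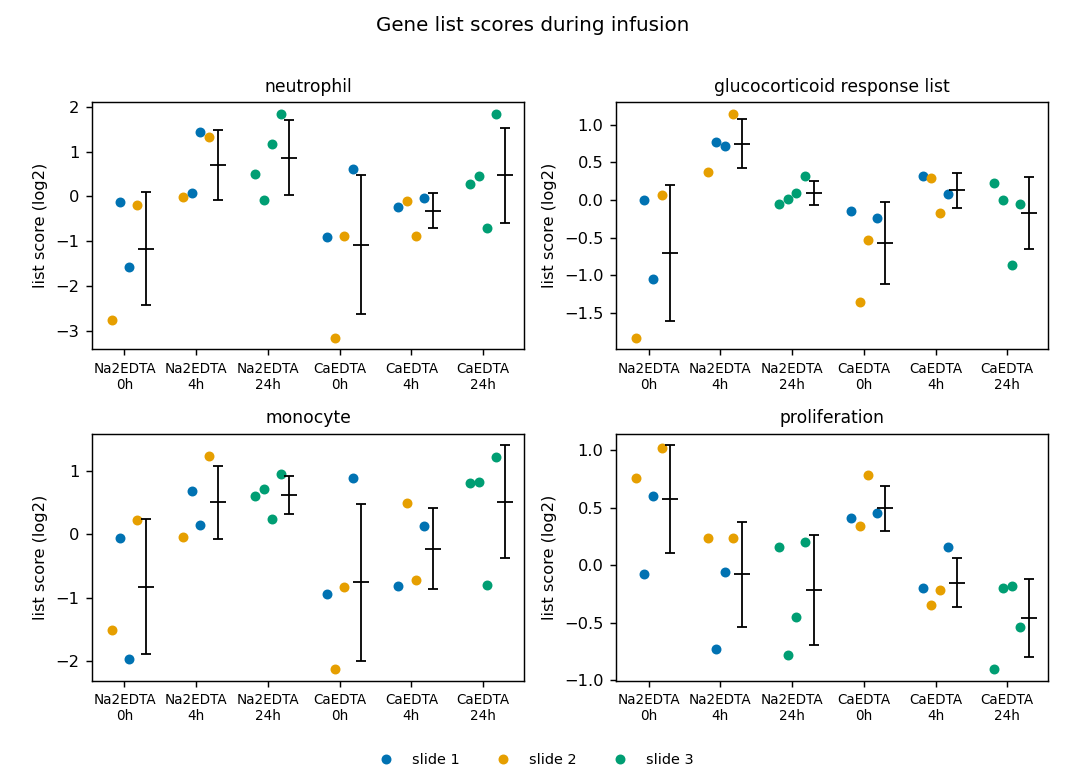
Scores of 4 gene lists on each array of the infusion study, as the median over members of the log2 signal relative to each member's mean. Points are arrays coloured by slide, and bars give the group's mean and SD (n = 4). The mean neutrophil score at 4 h was 0.71 in Na2EDTA and -0.32 in CaEDTA. The median of the members' fitted differences, which is not drawn, was 1.27.

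Before the infusions, the same contrast served as the baseline. At 0 h limma called 0 probes and, over all arrays, camera 0 lists. An unadjusted p under 0.05 was reached by 687 probes, against 635 at 4 h. The smallest unadjusted p belonged to ERCC2 of DNA repair (1.45 ± 0.33, adjusted p = 0.459), ARHGAP23 (0.499-fold, lower in Na2EDTA), NPB (1.19 ± 0.31), PABPN1 (0.74 ± 0.21) and TNFRSF21 (0.95 ± 0.27), the last 4 with an adjusted p of 0.742. At 0 h BIRC3 differed by 0.28, RAB26 by -0.04 and SLC49A4 by -0.15. A further term for the slide gave 0 calls at 0 h, with it as a block in place of the cow 1, within slides 1 and 2 by themselves 1 and 2. The count was 2 without cow 2. Within slide 1, with different cows in each infusion, camera called 5 lists at 0 h, all lower in Na2EDTA. They were monocyte (-1.05), neutrophil (-0.86), NK (-0.56), migration (-0.30) and unfolded protein response genes (-0.19). Within slide 2 it called T cell activation (-1.14) and hypoxia genes (0.57). Without the CaEDTA 0 h array of cow 3 it called NK (-0.48), oxidative phosphorylation (0.15) and ribosomal genes (0.25). With an estimated correlation the adjusted p of these 10 calls was 0.744 to 0.771, so none passed.

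From 0 h to 4 h of Na2EDTA, members of the neutrophil and glucocorticoid response lists were among the genes that rose. The beta-defensins DEFB13 (26.5-fold, 4.73 ± 0.77, adjusted p = 0.00883) and DEFB4A (4.63 ± 1.06) and the antimicrobial protein BPI (4.55 ± 0.81) had the largest rises. Also among the rises were TREM1, a receptor that amplifies inflammation in myeloid cells (3.19 ± 0.73), and CD14, the co-receptor for lipopolysaccharide (2.74 ± 0.57). DUSP1, a phosphatase that ends MAP kinase signals, rose 11.7-fold (3.54 ± 0.54, adjusted p = 0.00612). Also up were the transcription factor CEBPD (3.08 ± 0.70), CXCR4 (2.83 ± 0.55), ZBTB16 (1.81 ± 0.41), RGS2, a regulator of G-protein signals (2.86 ± 0.57), and CH25H, cholesterol 25-hydroxylase (3.17 ± 0.70). Among the falls were the small heat shock protein HSPB8 (-2.11 ± 0.33, adjusted p = 0.00641), the interferon lambda receptor IFNLR1 (-1.82 ± 0.29), TLR10 (-1.80 ± 0.31), the peptide apelin APLN (-1.71 ± 0.34), and stearoyl-CoA desaturase SCD (-1.66 ± 0.33). Smaller falls were those of CARNS1 (-1.57 ± 0.29), the lymphocyte receptor GPR18 (-1.42 ± 0.21), B3GALT2 (-1.38 ± 0.28), CXXC5 (-1.20 ± 0.26) and heparanase HPSE (-1.11 ± 0.17). In all, 93 probes changed, 61 up and 32 down.

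By list, 8 sets were higher and 4 lower at 4 h than at 0 h of Na2EDTA. The neutrophil list had a median of 2.38, with 14 of 14 members higher, 3 that rose over all probes and 8 adjusted over the list alone (adjusted p = 5.45e-07, and adjusted p = 0.188 with an estimated correlation). The glucocorticoid response list had a median of 1.36, 4 members that rose and 6 adjusted over the list alone (adjusted p = 1.01e-06, and 0.0802 as the adjusted p with an estimated correlation). In the monocyte list (median 1.38, adjusted p = 1.94e-05) CD14 rose. Adjusted over the list alone 7 members were higher, among them VCAN, a proteoglycan of monocytes (3.22 ± 0.77), and 1 lower. NK genes had a median of 0.83 with 6 passing adjusted over the list alone (adjusted p = 3.85e-06). The probe that stood for granulysin, GNLY, did not pass over all probes (1.70 ± 0.40, adjusted p = 0.0503), while its other probe did (1.88, adjusted p = 0.0394). With an estimated correlation the adjusted p was 0.289 for monocyte and 0.226 for NK genes. Interferon gamma, IFNG, rose (1.77 ± 0.35) within the T cell activation list (median 0.51, adjusted p = 0.013). Higher too were migration and adhesion (0.66, adjusted p = 0.00413), NF-kB and inflammatory cytokine genes (0.41, adjusted p = 0.0086, with TNF at -1.43 ± 0.39) and immediate early genes (0.42, adjusted p = 0.0395). An estimated correlation gave an adjusted p of 0.289 for T cell activation and for migration genes, 0.36 for NF-kB genes and 0.464 for immediate early genes.

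Lower at 4 h of Na2EDTA were proliferation genes (-0.61, 20 of 20 lower, none passing even over the list alone, adjusted p = 2.36e-06) and B cell genes (-0.69, 3 passing adjusted over the list alone, MS4A1 -0.95 ± 0.32, adjusted p = 0.00203). So were cholesterol synthesis genes (-0.36, HMGCS1 -0.79 ± 0.28, adjusted p = 0.0352) and oxidative phosphorylation genes (-0.20, NDUFV1 -0.40 ± 0.13, adjusted p = 0.00413). An estimated correlation gave an adjusted p of 0.289 for proliferation and cholesterol, 0.23 for B cell and 0.528 for oxidative phosphorylation genes. With the slide as a further term the immediate early list lost its call (adjusted p = 0.0994). Within slides 1 and 2 the medians were 1.86 and 2.77 for neutrophil, 1.30 and 0.94 for glucocorticoid, and 0.90 and 1.41 for monocyte genes. They were 0.59 and 1.33 for NK, 0.10 and 1.00 for T cell activation and 0.44 and 0.55 for migration genes. For NF-kB genes they were 0.71 and 0.50, and for immediate early genes 0.53 and 0.01. Among the lower lists they were -0.63 and -0.57 for proliferation, -0.57 and -0.65 for B cell, -0.33 and -0.43 for cholesterol and -0.15 and -0.22 for oxidative phosphorylation genes. In probe counts, the slide as a further term gave 610 calls, the slide as a block in place of the cow 65, and slides 1 and 2 by themselves 2 each. The count of 93 was 17 without the cow block (14 up, 3 down), 2, 76, 22 and 0 without cow 1, 2, 3 and 4, and 241 without the dimmest array (CaEDTA at 0 h of cow 3). It was 485 in a fit of these 2 groups alone, 828 with array weights, 159 with quantile normalization and 140 with an intensity trend. The balance was 45 up and 63 down with median centring, 57 and 70 with normexp and 38 and 34 with no filter.

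**Figure D2:**
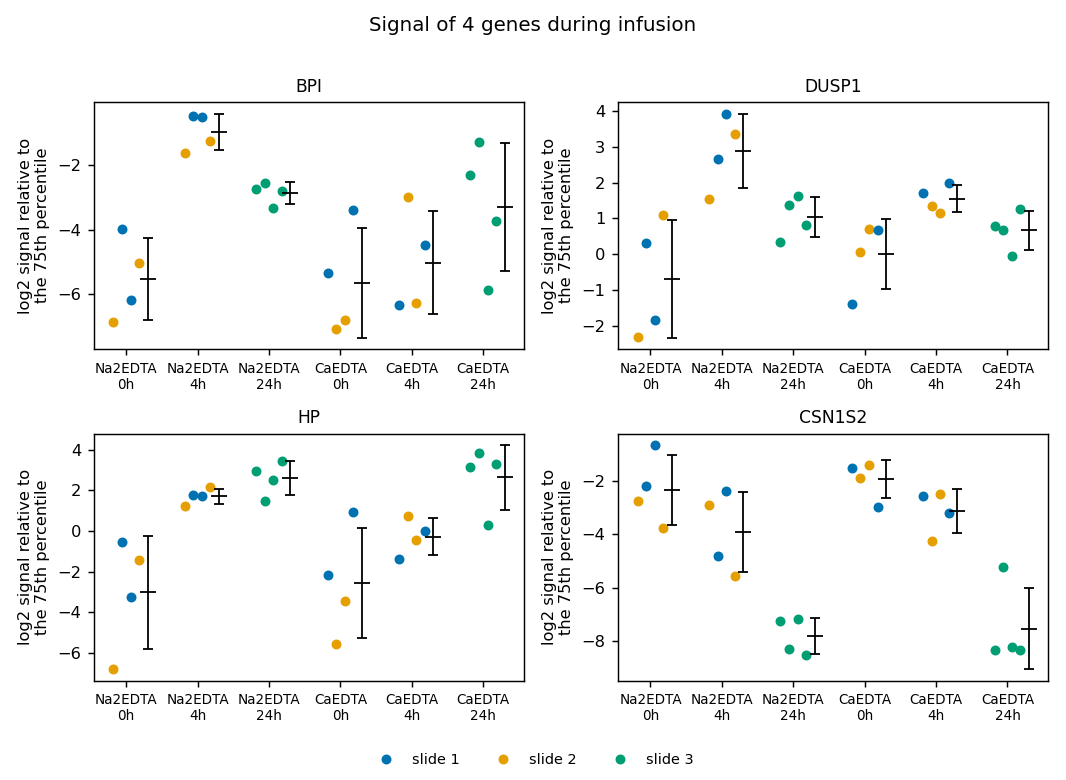
Signal of BPI, DUSP1, haptoglobin (HP) and the casein CSN1S2 on each array of the infusion study, as log2 signal relative to the array's 75th percentile. Points are arrays coloured by slide, and bars give the group's mean and SD (n = 4). From 0 h to 4 h of Na2EDTA, BPI rose by 4.55 ± 0.81 and DUSP1 by 3.54 ± 0.54 (log2 ± SE).

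In CaEDTA limma called 0 probes from 0 h to 4 h, with 1014 at an unadjusted p under 0.05. The named genes of smallest p were TIMM22 (-0.86 ± 0.16), POFUT2 (1.24 ± 0.23), YJU2B (1.39 ± 0.27), UBE3D (-0.84 ± 0.16) and MON1A (1.49 ± 0.29), each with an adjusted p of 0.106. Of the lists, proliferation genes were lower as they were under Na2EDTA (median -0.66, 19 of 20 lower, 7 passing adjusted over the list alone, AURKB -0.88 ± 0.27, NUSAP1 -1.02 ± 0.34, adjusted p = 1.32e-09, and adjusted p = 0.421 with an estimated correlation). So were oxidative phosphorylation genes (-0.18, adjusted p = 0.0032, with NDUFS8 at 0.52 ± 0.14 and SDHD at -1.19 ± 0.44). T cell genes (0.43, LCK 2.84-fold, adjusted p = 0.0153), NF-kB genes (0.45, GRO1 2.62 ± 0.83, adjusted p = 0.0235) and immediate early genes (0.54, DUSP1 1.54 ± 0.54, adjusted p = 0.0411) were higher. With an estimated correlation the adjusted p was 0.759 for oxidative phosphorylation and 0.668 for these other 3 lists. With 4 members at their bounds the NF-kB median was 0.26. Without the CaEDTA 0 h array of cow 3 the oxidative phosphorylation list lost its call (median -0.06, adjusted p = 0.171). Within slides 1 and 2 the medians were -0.38 and -0.81 for proliferation and -0.07 and -0.28 for oxidative phosphorylation genes. They were 0.21 and 0.59 for T cell, 0.12 and 0.76 for NF-kB and 0.38 and 0.41 for immediate early genes. A further term for the slide gave 62 calls, with it as a block in place of the cow 0, within slides 1 and 2 by themselves 0 and 11, and with array weights 97.

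The test of the difference between the infusions in the change from 0 h to 4 h called 2 probes, both unnamed and chosen after their values were seen. They were ABR3574 (2.33 ± 0.37) and ABR4281 (2.04 ± 0.33), each with an adjusted p of 0.0378. ABR4281 changed by 2.03 in Na2EDTA and by -0.01 in CaEDTA, and ABR3574 by 0.86 and -1.47. Named genes of smallest p were BIRC3 (-1.23 ± 0.23, adjusted p = 0.14), SAMSN1 (1.69 ± 0.38), SLC49A4 (2.11 ± 0.49), RAB26 (2.21 ± 0.53) and HMGCS1 of cholesterol synthesis (-1.64 ± 0.40). Camera called 7 lists. Neutrophil (1.45, adjusted p = 0.000325, BPI 3.92 ± 1.15), NK (0.84, adjusted p = 0.00118), glucocorticoid response (0.82, adjusted p = 0.000846, DUSP1 2.01 ± 0.77) and monocyte genes (0.66, adjusted p = 0.00238) were higher. B cell (-0.78, adjusted p = 0.00197, BLNK -0.95 ± 0.27), cholesterol (-0.41, adjusted p = 0.011) and calcium transport and sensing genes (-0.25, adjusted p = 0.0235, the calcium release channels ITPR3 -1.09 ± 0.37 and ITPR1 -0.78 ± 0.31) were lower. An estimated correlation gave an adjusted p of 0.304 for NK, 0.496 for monocyte and 0.275 for these other 5 lists. With the slide as a further term the calcium list lost its call (adjusted p = 0.0778). Without the CaEDTA 0 h array of cow 3 the glucocorticoid median was 0.40 and the monocyte median 0.37, both still called. Within slides 1 and 2, with different cows in each infusion, the medians were 1.85 and 1.00 for neutrophil, 0.66 and 1.04 for NK, 1.33 and 0.29 for glucocorticoid and 1.07 and 0.30 for monocyte genes. They were -0.74 and -0.65 for B cell, -0.29 and -0.60 for cholesterol and -0.43 and -0.33 for calcium genes. The 2 calls were 3 with the slide as a further term, 1 with it as a block in place of the cow, 0 within either slide, 1 without the cow block and 31 with array weights. None were called with median centring, quantile normalization, no filter, these 4 groups alone, without cow 2, 3 or 4, or without the CaEDTA 0 h array of cow 3.

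At 24 h limma called 0 probes between Na2EDTA and CaEDTA, with 20 at an unadjusted p under 0.05. That is far below a share of 0.05 of the 10305 probes tested, which unchanged probes would give on average. The fit takes its spread from all 24 arrays, which may not suit the 24 h arrays. The lack of calls thus does not show that the infusions did not differ at 24 h. The named genes of smallest p were SLC22A16 (at least 1.64-fold lower in Na2EDTA), CKMT2 (-1.46 ± 0.55), NUDCD1 (-0.82 ± 0.31), FOXP4 (0.56 ± 0.22) and MIS12 (-0.71 ± 0.29), each with an adjusted p of 1. Proliferation genes (0.24, 18 of 20 higher, AURKB 0.36 ± 0.27, adjusted p = 1.52e-05) and neutrophil genes (0.39, CATHL4 1.02 ± 0.82, adjusted p = 0.045) were higher as lists in Na2EDTA. Oxidative phosphorylation (-0.07, COX5A -0.29 ± 0.20, adjusted p = 0.00396), MHC class II and dendritic cell (-0.14, BOLA-DRB3 -0.43 ± 0.38, adjusted p = 0.0174) and unfolded protein response genes (-0.09, HSPA5 -0.26 ± 0.31, adjusted p = 0.045) were lower. Each had an adjusted p of 0.697 with an estimated correlation, and 0 members passed. On slide 3 alone, without the cow block, 0 probes were called, and the MHC class II (adjusted p = 0.0752), neutrophil (0.175) and unfolded protein response lists (0.078) lost their calls. The neutrophil (adjusted p = 0.0782) and unfolded protein response lists (0.0531) lost them too in the fit without the CaEDTA 0 h array of cow 3. The difference in the change from 0 h to 24 h gave 0 probes too, with 199 at an unadjusted p under 0.05, again below that share. They were led by PMPCB (-0.90 ± 0.27), ACACA (-1.58 ± 0.49), ARHGAP23 (1.06 ± 0.36), RBM26 (-1.74 ± 0.62) and MRPL13 (-0.87 ± 0.31), each with an adjusted p of 1. It called the MHC class II list alone (-0.42, 12 of 12 lower, BOLA-DQB -1.52 ± 0.70, adjusted p = 0.01, and adjusted p = 0.743 with an estimated correlation). The call was lost without the cow block (adjusted p = 0.166). It was also lost without the CaEDTA 0 h array of cow 3, with a median of -0.12 (adjusted p = 0.267, chosen after seeing the data), so it rests on that array.

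From 0 h to 24 h, haptoglobin, HP, an acute phase protein that binds haemoglobin, rose 49.2-fold in Na2EDTA (5.62 ± 1.11, adjusted p = 0.014) and 36.6-fold in CaEDTA (5.19 ± 1.11, adjusted p = 0.0215). In Na2EDTA the calgranulins S100A8 (3.89 ± 0.92) and S100A12 (3.43 ± 0.73) rose, as did DEFB4A (5.09 ± 1.06), DEFB13 (4.01 ± 0.77), and VCAN (4.16 ± 0.77). Other rises were those of CHI3L1 (3.64 ± 0.97), DGAT2 of triglyceride synthesis (3.60 ± 0.96), the monocyte lectin FCN1 (3.42 ± 0.77) and TREM1 (3.12 ± 0.73). In CaEDTA VCAN rose too (3.54 ± 0.77, with its other probe at 3.11 and an adjusted p of 0.0661), as did the defensin LAP (at least 3.44-fold) and the cytokine gene IL12B (at least 3.6-fold). Further rises in CaEDTA were those of HOGA1 (2.66 ± 0.64), the immunoglobulin A receptor FCAR (2.51 ± 0.49), ISG15, an interferon-induced ubiquitin-like protein (2.20 ± 0.43), EBD (2.16 ± 0.55), the apoptosis gene BAX (2.04 ± 0.40) and TASL (1.95 ± 0.51). Of these, IL12B, FCAR (2.41 ± 0.49), ISG15 (1.86 ± 0.43) and EBD (2.64 ± 0.55) were called as rises in Na2EDTA too. The casein gene CSN1S2 was called as a fall in both, at -5.45 ± 0.65 in Na2EDTA and -5.58 ± 0.65 in CaEDTA. Its signal was well above background on all 8 arrays at 0 h but on 2 of 8 at 24 h, so the size of the fall is not known.

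Among the other falls called in both infusions were NHERF1, a scaffold protein (-1.83 ± 0.28 in Na2EDTA and -1.72 ± 0.28 in CaEDTA), the tachykinin TAC3 (-1.89 ± 0.40 and -1.94 ± 0.40), SCD (-1.68 ± 0.33 and -1.46 ± 0.33), FKBP14 (-1.56 ± 0.30 and -1.31 ± 0.30) and CSRP2 (-1.17 ± 0.20 and -1.51 ± 0.20). LY96, which binds lipopolysaccharide with TLR4, rose on the probe that stood for it in Na2EDTA (0.96 ± 0.26, adjusted p = 0.0492) and was not called in CaEDTA (0.74 ± 0.26). Its other probe, outside the naming rule and chosen after its values were seen, fell in both, at least 4.05-fold and 6.64-fold. HSPB8 (-1.90 ± 0.33), P-selectin SELP (-1.88 ± 0.48), the immunoglobulin joining chain JCHAIN (-1.81 ± 0.49), BPGM (-1.80 ± 0.32) and APLN (-1.72 ± 0.34) fell past the threshold in Na2EDTA. In CaEDTA TGM2 (-2.12 ± 0.53), the channel TRPC4 (-1.84 ± 0.48), RRM2 of nucleotide synthesis (-1.69 ± 0.41), and the mitotic genes CDCA3 (-1.59 ± 0.39) and CCNB1 (-1.52 ± 0.37) fell. In Na2EDTA 353 probes changed, 170 up and 183 down, and in CaEDTA 368, 177 up and 191 down. The same direction was called in both for 141 probes, 48 up and 93 down, against 2.92 and 3.39 that unrelated lists of these sizes would share. Both comparisons came from 1 fit and set slide 3 against slides 1 and 2. A slide difference could thus enter both lists, and the overlap cannot be told apart from it. Log2 changes correlated at r = 0.77 across probes, which are not independent replicates. The difference between the infusions in this change was tested above and gave 0 probes.

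Monocyte genes were higher at 24 h as a list in Na2EDTA (median 1.56, 6 of 17 rose and 8 adjusted over the list alone, CD14 2.84 ± 0.57, adjusted p = 3.04e-07) and in CaEDTA (1.06, 1 rose and 10 adjusted over the list alone, adjusted p = 5.25e-05). Neutrophil genes had medians of 1.37 (5 of 14 rose, 6 adjusted over the list alone, adjusted p = 1.09e-05) and 1.28 (0 and 7, adjusted p = 0.00329). Proliferation genes were lower, by medians of -0.80 (2 of 20 fell, 12 adjusted over the list alone, CDK1 -1.26 ± 0.26, adjusted p = 3.04e-07) and -0.95 (8 fell, 15 adjusted over the list alone, CDK1 -1.28 ± 0.26, adjusted p = 6.49e-11). For the monocyte, neutrophil and proliferation lists the adjusted p with an estimated correlation was 0.429, 0.429 and 0.49 in Na2EDTA and 0.48, 0.486 and 0.291 in CaEDTA. Ribosomal protein genes (0.40 and 0.41, RPS19 0.91 ± 0.31 in Na2EDTA and RPS3 0.98 ± 0.35 in CaEDTA) and migration and adhesion genes (0.52 and 0.69, ICAM3 0.79 ± 0.32 and 0.81 ± 0.32) were higher in both. The adjusted p was 0.00948 and 0.00422 for ribosomal and 0.0201 and 0.0397 for migration genes. An estimated correlation gave an adjusted p of 0.596 and 0.726 for ribosomal and 0.49 and 0.615 for migration genes. T cell genes (0.44, CD3D 1.22 ± 0.39, adjusted p = 0.0344) and glucocorticoid response genes (0.61, CEBPD 2.43 ± 0.70, adjusted p = 0.0344) were called in Na2EDTA, both with an adjusted p of 0.49 with an estimated correlation. The hypoxia and glycolysis list was called in CaEDTA (0.63, 2 of 18 rose, LDHA 1.01 ± 0.27 and TPI1 0.66 ± 0.17, 6 adjusted over the list alone, adjusted p = 0.00647, and 0.48 as the adjusted p with an estimated correlation). Without the CaEDTA 0 h array of cow 3 the migration list of CaEDTA (0.49, adjusted p = 0.0689) and the glucocorticoid list of Na2EDTA (adjusted p = 0.0572) lost their calls, and the ribosomal median of CaEDTA was 0.62.

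All 24 h arrays lay on slide 3 and all 0 h arrays on slides 1 and 2, so slide and time cannot be told apart in these changes. With the slide as a random block, chosen after seeing the data, 3 probes were called in each infusion. The counts of 353 and 368 were 63 (18 up, 45 down) and 86 without the cow block, 0 and 1 in fits of the 2 groups alone, 8 and 27 without cow 1, 189 and 89 without cow 2, 29 and 17 without cow 3, and 19 and 27 without cow 4. They were 596 and 92 without the CaEDTA 0 h array of cow 3, 1545 and 1472 with array weights, and 191 and 191 at a log2 change of at least 1. Counts of 729 (195 up, 534 down) and 611 (186 up, 425 down) came with another background correction, normexp. No filter gave 263 (88 up, 175 down) and 118, and median centring in Na2EDTA 331 (122 up, 209 down).

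Milk fever cows that recovered after a single treatment (group A, n = 4) were compared with healthy cows (n = 5). PTX3, a secreted pattern recognition protein, was 79.6-fold higher in group A (6.31 ± 1.40, adjusted p = 0.0386), IL1R2 10.3-fold (3.36 ± 0.69) and the complement receptor C5AR1 8.12-fold (3.02 ± 0.62). Also higher were the kinase NUAK1 (4.77 ± 1.01), AVPI1 (3.55 ± 0.85), and CD24 (3.02 ± 0.76). So were the milk protein beta-lactoglobulin PAEP (2.60 ± 0.32), HIF1A, the oxygen-regulated transcription factor (2.55 ± 0.56), and the metalloproteinase inhibitor TIMP4 (2.29 ± 0.38). PAEP was dim in group H, at -7.98 to -7.33 relative to the 75th percentile. The dimmest signals well above background there were -8.60 to -7.95, so its difference may include one of background. Lower were ADAP1 (-2.30 ± 0.23, adjusted p = 0.00098), the keratin KRT35 (-2.27 ± 0.27), the channel KCNK5 (-2.24 ± 0.51), and ID3, an inhibitor of transcription factors in lymphocytes (-2.20 ± 0.52). Also lower were PKLR (-2.02 ± 0.38), NPBWR2 (-1.96 ± 0.25), DYNLT2B (-1.94 ± 0.34), PPM1G (-1.85 ± 0.22), ZBTB9 (-1.80 ± 0.41) and ZNF410 (-1.79 ± 0.34). The other ZNF410 probe was not called (-0.43, adjusted p = 0.549). In all, 374 probes differed, 231 higher and 143 lower in group A.

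By list, NF-kB and inflammatory cytokine genes had the largest median in group A (2.92, 24 of 26 higher, 1 passing over all probes, NFKB1 1.35 ± 0.29, and 13 adjusted over the list alone, among them IL1B 3.89 ± 1.17, adjusted p = 1.89e-06). Glucocorticoid response genes followed (1.55, 4 of 13 passing over all probes, IL1R2, CXCR4 1.75 ± 0.39, CEBPD 2.01 ± 0.50 and the glucocorticoid receptor NR3C1 0.99 ± 0.24, and 9 higher adjusted over the list alone, adjusted p = 0.0028). The other NR3C1 probe was at 0.22 (adjusted p = 0.53). Immediate early genes (1.12, EGR1 1.72 ± 0.50, adjusted p = 0.0142), monocyte genes (0.87, 7 adjusted over the list alone, CD14 2.75 ± 0.84, adjusted p = 0.000581) and hypoxia and glycolysis genes (0.56, HIF1A and the glucose transporter SLC2A3 2.04 ± 0.47 passing, 6 adjusted over the list alone, adjusted p = 0.00458) were higher too. T cell (-1.02, CD3D -2.37 ± 0.97, adjusted p = 0.00697) and B cell (-0.90, 3 adjusted over the list alone, CD79A -1.11 ± 0.32, adjusted p = 0.0119) genes were lower. Proliferation (-0.69, CCNB2 passing at -1.17 ± 0.27, 5 adjusted over the list alone, adjusted p = 0.0028) and interferon response genes (-0.65, MX1 -2.32 ± 0.65, 5 adjusted over the list alone, adjusted p = 0.0028) were lower too. With an estimated correlation the adjusted p was 0.691 for immediate early and T cell genes and 0.667 for these other 7 lists. Without array A 3, which stood apart from the others, the T cell (-0.58, adjusted p = 0.0955) and B cell lists (-0.59, adjusted p = 0.112) lost their calls and the NF-kB median was 1.89. Over all arrays, with 1 member at its bound, that median was 2.51. Groups A and H lay on a slide each, so slide and group cannot be told apart. The count of 374 was 22, 2202, 129 and 1385 without A 1 to A 4, 130, 174, 110 and 295 without B 1 to B 4, and 42, 35, 43, 86 and 147 without H 1 to H 5. It was 2427 with normexp (1901 higher, 526 lower), 143 with median centring (67 higher, 76 lower), 535 with quantile normalization (220 higher, 315 lower) and 3780 with no filter (3109 higher, 671 lower). It was 583 with the filter on every array, 193 with array weights (70 higher, 123 lower), 14 in a fit of these 2 groups alone and 2095 in a fit of all 37 arrays (1064 higher, 1031 lower).

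**Figure D3:**
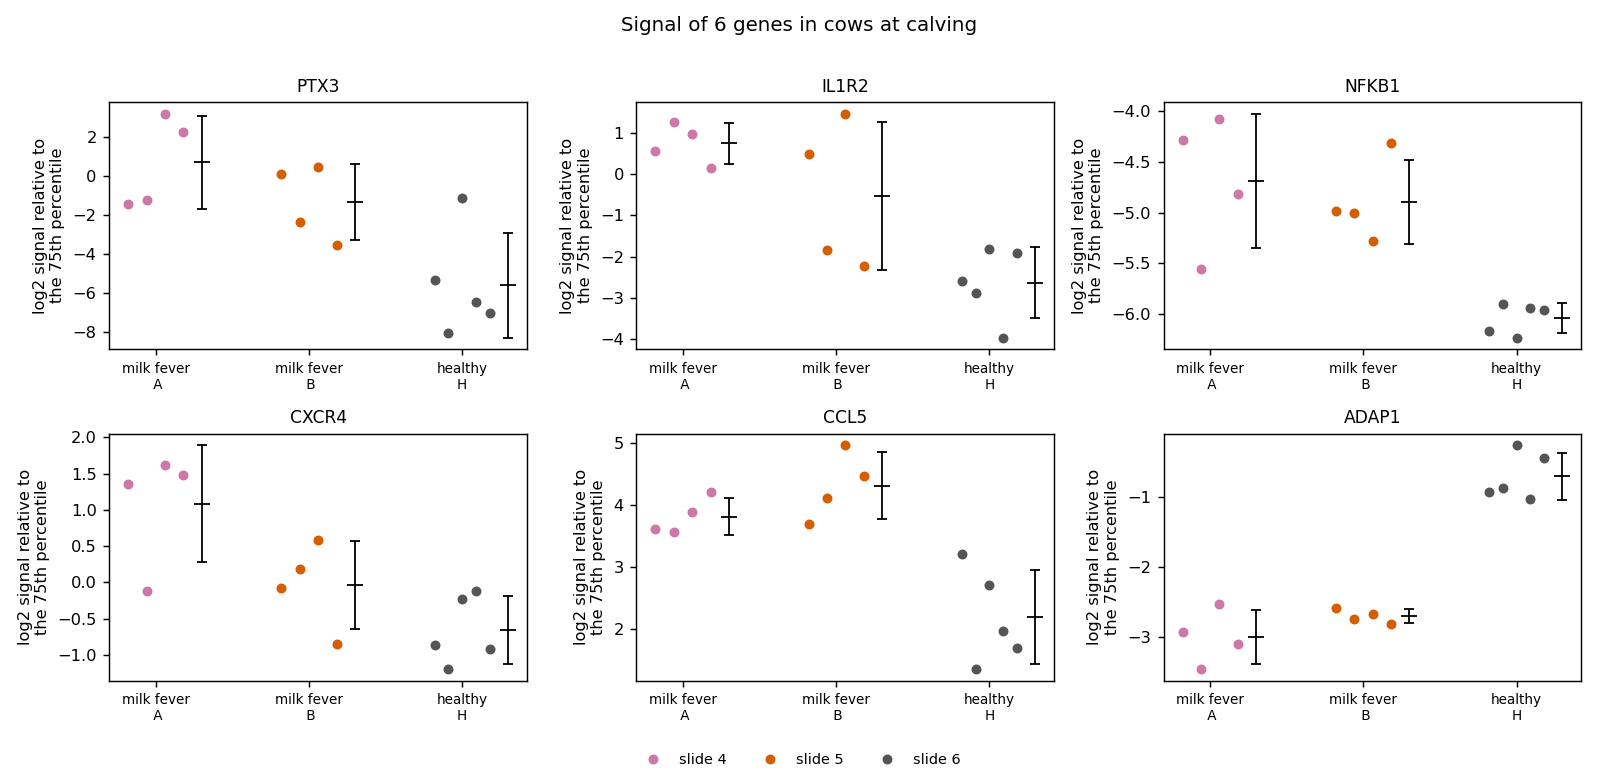
Signal of PTX3, IL1R2, NFKB1, CXCR4, CCL5 and ADAP1 on each array of the cows at calving, as log2 signal relative to the array's 75th percentile. Points are arrays coloured by slide, and bars give the group's mean and SD (n = 4 in groups A and B, n = 5 in group H). PTX3 was higher in group A than in group H by 6.31 ± 1.40 and ADAP1 lower, at -2.30 ± 0.23 (log2 ± SE).

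Milk fever cows that needed further treatment (group B, n = 4) differed from healthy cows (n = 5) in 62 probes, 36 higher and 26 lower. FBN1, the matrix protein fibrillin (at least 5.61-fold), the chemokines CCL14 (3.06 ± 0.58) and CCL5 (4.38-fold, 2.13 ± 0.37, adjusted p = 0.0263) and the T cell co-stimulator CD80 (1.52 ± 0.20) were higher. So were ACR (2.72 ± 0.51), ACTL9 (2.08 ± 0.33), SIPA1L3 (2.02 ± 0.28), TIMP4 (1.89 ± 0.38), the channel ASIC1 (1.74 ± 0.33) and IGFBP5 (1.51 ± 0.27). ACTL9 was dim in group H, at -8.35 to -7.56 relative to the 75th percentile. The dimmest signals well above background there were -8.60 to -7.95, so its difference may include one of background. Apolipoprotein E, APOE (-1.25 ± 0.21), the nucleoside transporter SLC29A1 (-1.22 ± 0.24), KRT35 (-2.10 ± 0.27), ADAP1 (-1.99 ± 0.23), NPBWR2 (-1.83 ± 0.25) were lower, and so were PATL1 (-1.39 ± 0.27), RPH3AL (-1.38 ± 0.27), PROK1 (-1.36 ± 0.22), SSPO (-1.22 ± 0.23) and LRRTM1 (-1.09 ± 0.19). NF-kB genes (2.05, 25 of 26 higher, 1 adjusted over the list alone, NFKB1 1.14 ± 0.29, OSM 4.44 ± 1.35, adjusted p = 5.56e-05) and immediate early genes (1.49, 7 adjusted over the list alone, EGR1 2.04 ± 0.50, adjusted p = 0.000252) were higher as lists. NK genes (1.23, 3 adjusted over the list alone, NKG7 1.46 ± 0.36, adjusted p = 0.0105) and glucocorticoid response genes (0.67, 6 adjusted over the list alone, GLUL 1.19 ± 0.42, adjusted p = 0.013) were higher too. Proliferation (-0.46, CDK1 -1.12 ± 0.39, adjusted p = 0.000387) and heat shock genes (-0.25, DNAJB1 -0.62 ± 0.27, adjusted p = 0.0105) were lower, and no list member passed over all probes. With 1 member at its bound the NF-kB median was 1.88 and the heat shock median -0.23. The adjusted p with an estimated correlation was 0.796 for NF-kB genes and 0.723 for these other 5 lists. Slide and group cannot be told apart here either. The count of 62 was 59, 94, 169 and 77 without A 1 to A 4, 14, 14, 6 and 34 without B 1 to B 4, and 30, 11, 36, 36 and 21 without H 1 to H 5. It was 35 with median centring (11 higher, 24 lower), 81 with quantile normalization (14 higher, 67 lower), and 2276 with no filter (2125 higher, 151 lower). It was 27 with the filter on every array (10 higher, 17 lower), 1679 with array weights and 280 in a fit of these 2 groups alone.

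Between the milk fever groups, which asks what set apart the cows that needed more treatment, limma called 0 probes, with 1126 at an unadjusted p under 0.05. The named genes of smallest p were FXYD3 (1.37 ± 0.23, adjusted p = 0.0625), CIT (at least 1.24-fold higher in group B, adjusted p = 0.123), and PAEP (-1.78 ± 0.34, adjusted p = 0.149). TBATA (adjusted p = 0.0537) and UGT1A6 (adjusted p = 0.117) were among them too, but no array of group A was well above background and the bound reached no fold above 1. Monocyte genes were lower in group B as a list (-0.58, 18 of 19 lower, TLR2 -0.85 ± 0.43, CD68 -1.36 ± 0.71, adjusted p = 0.000792, and 0.83 as the adjusted p with an estimated correlation). Ribosomal protein genes were too (-0.14, RPL7 -0.29 ± 0.20, adjusted p = 0.011, and 0.83 as the adjusted p with an estimated correlation), but not without array A 3 (median 0.02, adjusted p = 0.896). The count of 0 was 4 without A 1, 3 without B 1, 2 with quantile normalization, 41 with array weights and 1 in a fit of all 37 arrays. Slide and group cannot be told apart.

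Both milk fever groups taken as 1, with equal weight, differed from healthy cows in 420 probes, 276 higher and 144 lower. PTX3 (39.3-fold, 5.30 ± 1.19, adjusted p = 0.0377), NUAK1 (4.04 ± 0.86), FBN1 (at least 2.48-fold), IL1R2 (2.73 ± 0.59), and NFIL3, a transcription factor of innate lymphocytes (2.72 ± 0.62) were higher, as were CCL14 (2.60 ± 0.49), C5AR1 (2.46 ± 0.53), ACR (2.43 ± 0.43) and RGS16 (2.36 ± 0.58). KRT35 (-2.19 ± 0.23), ADAP1 (-2.14 ± 0.19), HEY1 (-2.10 ± 0.48), KCNK5 (-2.06 ± 0.43), ID3 (-2.03 ± 0.44), NPBWR2 (-1.90 ± 0.21), ZBTB9 (-1.58 ± 0.35), ZNF410 (-1.57 ± 0.29, other probe -0.31, adjusted p = 0.638), DYNLT2B (-1.56 ± 0.29) and TBCC (-1.56 ± 0.40) were lower. NF-kB (2.55, NFKB1 passing at 1.25 ± 0.25, 19 higher and 1 lower adjusted over the list alone, adjusted p = 1.21e-06) and immediate early (1.39, EGR1 passing at 1.88 ± 0.43, 9 adjusted over the list alone, adjusted p = 0.002) genes were higher. Glucocorticoid response (1.19, IL1R2, CEBPD and NR3C1 passing, 8 adjusted over the list alone, adjusted p = 0.00259), monocyte (0.58, ITGAM 1.22 ± 0.37, adjusted p = 0.00552) and hypoxia and glycolysis genes (0.40, SLC2A3 and HIF1A passing, 3 adjusted over the list alone, adjusted p = 0.00719) were higher too. T cell (-0.84, CD28 -1.02 ± 0.37, adjusted p = 0.0141) and B cell (-0.63, adjusted p = 0.0415) genes were lower. Proliferation (-0.59, CCNB2 and MCM5 passing, at -0.99 ± 0.23 and -0.82 ± 0.21, and 2 adjusted over the list alone, adjusted p = 0.000608), interferon response (-0.57, CXCL10 -1.97 ± 0.58, adjusted p = 0.00552) and heat shock genes (-0.28, STIP1 -0.56 ± 0.23, adjusted p = 0.0415) were lower too. With 1 member at its bound the NF-kB median was 2.24. Each of these 10 lists had an adjusted p of 0.733 with an estimated correlation. Without A 3 the T cell (-0.47, adjusted p = 0.0626) and B cell lists (-0.47, adjusted p = 0.14) lost their calls, and the interferon response median was -0.33, still called (adjusted p = 0.0145). A random block for the slide gave 122 calls (61 higher, 61 lower). Group H had a slide to itself, so this block cannot remove a slide difference from group H. Slide and group cannot be told apart here either. The count of 420 was 133, 1439, 494 and 583 without A 1 to A 4, 122, 108, 96 and 619 without B 1 to B 4, and 96, 93, 83, 155 and 183 without H 1 to H 5. It was 2854 with normexp (2411 higher, 443 lower), 187 with median centring (77 higher, 110 lower), 395 with quantile normalization (126 higher, 269 lower) and 3605 with no filter (3112 higher, 493 lower). It was 255 at a log2 difference of at least 1, 1342 with array weights and 1321 in a fit of all 37 arrays.

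Groups A and B shared 42 probes that differed from healthy cows in the same direction, 20 higher and 22 lower. Among them CCL5, TIMP4, ACR, TET2, ASIC1, PLA2G2D1 and CD80 were higher in both and KRT35, ADAP1 and NPBWR2 lower in both. TET2, an enzyme of DNA demethylation, was higher by 1.70 in group A and 1.46 in group B, and the phospholipase PLA2G2D1 by 1.40 and 1.63. Unrelated lists of these sizes would share 0.682 and 0.305 probes. Both comparisons used the same 5 healthy arrays, and simulated unchanged groups against such shared arrays had 0.02 probes in common on average and 1 at most. The simulation drew each probe independently and held no slide effect. Group H lay on a slide of its own, so a slide difference could enter both lists, and the overlap cannot be told apart from it. With the healthy cows split 2 and 3 between the comparisons, the overlap was 0 to 7 probes over 20 splits, with a median of 0.5. Log2 differences correlated at r = 0.73 across probes, against 0.44 in the simulation and 0.459 to 0.598 with split healthy cows. Probes are not independent replicates. The difference between groups A and B was tested above and gave 0 probes.

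Induced and spontaneous hypocalcaemia were compared through the calls of Na2EDTA against CaEDTA at 4 h and of milk fever against healthy cows, which share no array. Of the 8 and 190 probes higher in each and tested in both, 3 were shared, against 0.148 for unrelated lists (Fisher's exact test, two-sided, p = 0.000326, and 0.000868 adjusted over 8 pairs of comparisons). This test takes probes as independent, which they are not, so its p does not measure the spread between cows. The milk fever calls cannot be told apart from the slide either. The shared probes were ABR5229, ABR4281 and ABR2522, unnamed and chosen after their values were seen. Their log2 differences were 2.61, 1.87 and 2.01 at 4 h and 1.51, 2.14 and 1.96 in milk fever. No probe was lower in both, and no gene with a symbol was shared. Glucocorticoid response, monocyte and hypoxia lists were higher and T cell and B cell lists lower in both comparisons, each with the adjusted p given above. None of these lists passed in either comparison with an estimated correlation, and without A 3 the T cell and B cell lists were not called in milk fever. The T cell and hypoxia lists were not called in the difference between the infusions in the change to 4 h. From 0 h to 4 h the mean T cell score rose in both infusions, from -0.36 to 0.08 in Na2EDTA and from -0.18 to 0.36 in CaEDTA. At 0 h the mean B cell score was 0.34 in Na2EDTA and -0.14 in CaEDTA. Among the 93 probes changed from 0 h to 4 h of Na2EDTA, 7 were called in the same direction in milk fever. The glucocorticoid-induced CEBPD (3.08 ± 0.70 and 1.71 ± 0.43) and the kinase inhibitor PKIB were among the 6 higher, and CSRP2 was the 1 lower. Log2 differences at 4 h and in milk fever correlated at r = 0.35 across probes, which are not independent replicates. Without the cow block the overlap was 3 probes too.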

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

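The tests of neutrophil number, milk RNA, background on the healthy slide and lymphocyte share were chosen after the results were seen, as was reading the slide test of neutrophil genes against 0, and the tests of slides and of other splits before.

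Neutrophil genes were higher at 4 h of Na2EDTA than of CaEDTA, by a median of 1.27 (0.92 with 2 members at bounds), and a slide difference shared by the groups is argued against as the whole of it, since slides 1 and 2 each hold 2 arrays of either group. With the slide as a term the list score differed by 1.03 ± 0.578 (SE), above 0 by more than its SE though above the 0.5 set beforehand by less. That term cannot move the difference where the slides are balanced over the groups, so its value decides nothing further. Within slides 1 and 2 the score differed by 0.901 and 1.15, each between 2 cows and 2 other cows. More neutrophils among the collected cells is a candidate explanation that stays open: of their abundant genes S100A8 differed by 1.14 ± 0.92 and S100A12 by 0.67 ± 0.73, the latter by less than its SE. Density separation would remove most neutrophils, monocytes express the S100 genes too, and none of the list's genes is in another list. A change of expression within the cells under Na2EDTA was not tested apart from cell number.

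The arrays at 24 h differed from those at 0 h in both infusions, with 353 and 368 called probes. To test a slide difference, probes called at 24 h of Na2EDTA were followed in the change from 0 h to 4 h of CaEDTA, on slides 1 and 2 and with none of the same 0 h arrays. The rises moved the same way there by a median of 0.240 ± 0.264 (SE over cows) and the falls by 0.176 ± 0.0779, both between the bounds set beforehand of 0.1 and 0.3, so slide and time cannot be told apart for either. The CSN1S2 signal was well above background on 8 of 8 arrays at 0 h, while probes of the other milk genes CSN1S1, CSN3 and LALBA were so on 0 of 8. This argues against milk RNA as its source only if those probes detect milk RNA where it is present, which was not tested. The milk protein gene PAEP was not part of this test. An effect of sampling and infusion as such, shared by Na2EDTA and CaEDTA, stays open and was not tested.

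Group A differed from group H in 374 probes. A slide difference stays open, since the probes higher in group A moved the same way from 0 h to 4 h of Na2EDTA, on other slides and in other cows, by a median of 0.149 ± 0.183 (SE). A lower background on the slide of group H stays open too: 3.15% of the probes well above background on all 13 arrays were called and 2.87% of the others (Fisher's exact test, two-sided, p = 0.450). A lower share of lymphocytes would raise the markers of all other cell types alike. The monocyte, neutrophil and platelet lists had medians of 0.87, 0.80 and 0.12, a spread of 0.751. The SE of a single list's score difference was up to 0.407, and no SE of the spread itself was computed. A lower share of lymphocytes thus cannot be excluded. Milk fever as such stays open and cannot be told apart from the slide.

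Other splits of the arrays into groups of the same sizes were refitted. For group A against H, group B against H, and both against H, of 100 splits only 1, the real one, gave as many calls. The real counts were 374, 62 and 420, against at most 2, 3 and 8 in the others. Chance alone can be excluded by this, but a slide difference cannot. Groups A, B and H had a slide each, so the real split follows the slides, and the counts cannot tell milk fever from the slide. For group B against A the real count is 0, which all 35 splits reach by construction, so the count decides nothing about chance. The highest other split called 589 probes, which points to a structure of the samples. In the infusion study each comparison has 8 splits that part the pairs, too few for a share under 0.05. The real count and the highest other were 93 and 0 from 0 h to 4 h of Na2EDTA, and 0 and 1 of CaEDTA. They were 353 and 0 and 368 and 17 from 0 h to 24 h of Na2EDTA and CaEDTA, and 0 and 34 between the infusions at 24 h. They were 10 and 1142 between the infusions at 4 h, 0 and 3103 at 0 h, and 2 and 7 for the difference in the change from 0 h to 4 h. There the highest split follows the slides and points to a structure by slide, or by what else parts the cows and infusions in the same way. The same parting at 24 h, with all arrays on slide 3, gave the 34 calls. No term for the order of the infusions in the crossover was fitted, so its part in this was not tested. At 0 h, splits that do not follow the slides called up to 125 probes when they part the pairs and 111 when they keep some whole, against the real 0. The structure at 0 h is not by slide alone, and its source was not tested. With the slide as a term the real counts at 4 h, at 0 h and for that difference were 32, 0 and 3, and within slides 1 and 2 they were 2 and 1, 1 and 2, and 0 and 0. For the difference in the change from 0 h to 24 h they were 0 and 189, which points to a structure of the samples. That split parts the 0 h arrays by slide, while all 24 h arrays lay on slide 3, and what else it follows was not tested. Of 27 splits that keep some pairs whole, the one that follows the slides called 3280 probes from 0 h to 4 h of Na2EDTA and 3403 of CaEDTA, again a structure by slide or by what else parts these arrays so. With the slide as a term the real counts there were 610 and 62, and within slides 1 and 2 they were 2 and 2, and 0 and 11.

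The change from 0 h to 4 h differed between the infusions, by the test of the difference itself, for 2 probes, ABR4281 (2.04) and ABR3574 (2.33), and for the medians of the NK (0.84), B cell (-0.78), monocyte (0.66), neutrophil (1.45), calcium transport (-0.25), glucocorticoid (0.82) and cholesterol lists (-0.41). None of these 7 lists passed with an estimated correlation (adjusted p 0.275 to 0.496), and the calcium list lost its call with the slide as a term (adjusted p = 0.0778). The change from 0 h to 24 h differed for the MHC class II list (-0.42), but not with an estimated correlation (adjusted p = 0.743), without the cow block (adjusted p = 0.166) or without the CaEDTA 0 h array of cow 3 (adjusted p = 0.267), an alternative chosen after seeing the data.

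Single arrays stood far from the other arrays of their group in 23 of 612 groups of values, and chance gives about 1 in 20. The value in each case below is the gap to the nearest array as a share of the group's range. Array 3 of CaEDTA at 24 h had 70.7% of probes well above background against 66.4% to 66.8% (0.916). The MHC class II score of CaEDTA at 0 h was -0.99 on array 3 against 0.03 to 0.15 (0.90). The difference in that list's change to 24 h rests on this array. The immediate early score of Na2EDTA at 4 h was 0.52 on array 4 against 0.01 to 0.04 (0.942). The ribosome score of group B was 0.04 on array 1 against -0.12 on the others (0.982). In the infusion study, gaps were found for CSN1S2 in CaEDTA at 24 h (array 2, 0.961), LAP there (array 3, 0.964), IL12B (array 4, 0.842) and ITPR3 (array 3, 0.840) in CaEDTA at 0 h, HSPB8 (array 4, 0.928) and EBD (array 4, 0.887) in Na2EDTA at 24 h, and IFNLR1 (array 2, 0.892) in Na2EDTA at 4 h. In group A, gaps were found for CXCR4 (array 2, 0.852), NFIL3 (array 2, 0.840), STIP1 (array 1, 0.977) and NR3C1 (array 3, 0.921), and in group B for FBN1 (array 1, 0.934). In group H, they were found for CD14 (0.928), PAEP (0.950), SLC2A3 (0.738) and PATL1 (0.797) on array 4, CD79A on array 3 (0.804), HEY1 on array 5 (0.854) and ACTL9 on array 2 (0.776).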

How the results depend on the processing

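The fit with the slide as a random block for the change to 24 h, the fits without the CaEDTA 0 h array of cow 3, and the list medians with the slide, within slides, without array A 3, without that CaEDTA array and with bounds for dim genes were chosen after seeing the data. Counts are of called probes, and the cause of a move was not tested unless the setting itself leaves fewer arrays or probes. With the deposited value table the counts were 88 for 93 at 4 h against 0 h of Na2EDTA, and 349 for 353 and 364 for 368 at 24 h against 0 h. They were 418 for 420 in both milk fever groups, and the same elsewhere. Of 5105 values of genes named above under all settings, 3849 kept their direction and side of the threshold, 1139 kept the direction alone, 114 newly passed and 3 changed sign without passing. These were MON1A from 0 h to 4 h of CaEDTA (-0.0564 with normexp), TNFRSF21 at 0 h (-0.23 within slide 1) and HSPA5 at 24 h (-0.50 to 0.10 with a cow left out). Signal over background sets what could be tested, 10305 and 12190 of 15208 probes. Normexp moved the median of all probes by -0.14 and -0.16 in the change to 24 h of Na2EDTA and CaEDTA, and against group H by 0.21 in group A, 0.10 in group B and 0.15 in both. Quantile normalization moved it by -0.11 in group A and -0.11 in both. Median centring moved it by -0.11 and -0.13 in the change to 4 h of Na2EDTA and CaEDTA, -0.11 in group B against H and -0.11 against A. No filter moved it by -0.16 and -0.22 in the change to 4 h and 24 h of Na2EDTA, -0.16 in the change to 24 h of CaEDTA, -0.13 between the infusions at 4 h and -0.20 in the difference in the change to 4 h. Against group H it moved it by 0.19 in group A, 0.13 in group B and 0.15 in both.

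Between the infusions at 4 h, the count of 10 was 6 with normexp, 2 with no filter, 4733 with array weights, and 3 without the block. It was 32 with the slide as a term, 2 and 1 within slides 1 and 2, 0 in a fit of the 2 groups, and 1 to 12 with a cow or array left out. At 0 h, the count of 0 was 1 with the slide as a block, 1 and 2 within slides 1 and 2, and 0 to 2 with a cow or array left out. At 24 h it was 0 in each fit run. From 0 h to 4 h of Na2EDTA, the count of 93 was 159 with quantile normalization, 140 with an intensity trend, 828 with array weights and 17 without the block. It was 610 with the slide as a term, 2 within slide 1 and 2 within slide 2, 485 in a fit of the 2 groups, and 0 to 241 with a cow or array left out. In CaEDTA at 4 h against 0 h, the count of 0 was 97 with array weights, 62 with the slide as a term, 11 within slide 2 and 0 with any cow left out. For the difference in that change, the count of 2 was 0 with quantile normalization, median centring, no filter, slide 1, slide 2 or the groups compared alone. It was 31 with array weights, 1 without the block, 1 with the slide as a block, and 0 to 2 with a cow or array left out.

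In Na2EDTA at 24 h against 0 h, the count of 353 was 729 with normexp, 1545 with array weights, 191 at a log2 change of at least 1 and 63 without the block. It was 0 in a fit of the 2 groups, 3 with the slide as a random block, and 8 to 596 with a cow or array left out. In CaEDTA, the count of 368 was 611 with normexp, 118 with no filter, 1472 with array weights, 191 at a log2 change of at least 1 and 86 without the block. It was 1 in a fit of the 2 groups, 3 with the random block, and 17 to 92 with a cow or array left out. The slide as a fixed term could not be fitted for these changes, as the 24 h arrays have a slide of their own.

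For group A against H, the count of 374 was 2427 with normexp, 143 with median centring, 3780 with no filter, and 583 with the filter on every array. It was 193 with array weights, 111 with the title numbers as a block, 14 in a fit of the 2 groups, 2095 in a fit of 37 arrays, and 22 to 2202 with an array left out. For group B against H, the count of 62 was 35 with median centring, 2276 with no filter, and 27 with the filter on every array. It was 1679 with array weights, 9 with the title numbers as a block, 280 in a fit of the 2 groups, and 6 to 169 with an array left out. For group B against A, the count of 0 was 2 with quantile normalization, 41 with array weights, 1 in a fit of 37 arrays, and 0 to 4 with an array left out. For both against H, the count of 420 was 2854 with normexp, 187 with median centring, 3605 with no filter, and 1342 with array weights. It was 255 at a log2 difference of at least 1, 138 with the title numbers as a block, 1321 in a fit of 37 arrays, 122 with the slide as a random block, and 83 to 1439 with an array left out. The random block cannot remove a slide difference from group H, which had a slide to itself. The 79 list calls were 0 with an estimated correlation and 15 with fry. They were 75 with quantile normalization (68 of them among the 79), 92 with median centring (79 of the 79 among them) and 76 without the cow block (75 of them among the 79). The overlap of groups A and B, 42 probes, had a median of 0.5 with the healthy cows split.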

Other observations

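Some genes stood out at 4 h of Na2EDTA against CaEDTA inside lists that were not called as a whole. They passed adjusted over the list alone and not over all probes, and were chosen after their values were seen. Of the MHC class II and dendritic cell list, BOLA-DYB (1.16 ± 0.26) and BOLA-DOB (0.93 ± 0.27) were higher. Of the fatty acid oxidation and PPAR list, the adipogenic receptor PPARG (1.61 ± 0.47) and the carnitine carrier SLC25A20 (0.73 ± 0.21) were higher and the lipoprotein lipase inhibitor ANGPTL4 lower (-0.96 ± 0.28). Of the NF-kB list, IL12B was higher (2.22 ± 0.68) and IL6 lower (at least 1.54-fold), and of the apoptosis list, the pro-apoptotic BCL2L11 was higher (0.79 ± 0.25). At 0 h 2 B cell genes passed in the same way, BTK (0.93 ± 0.34) and BLNK (0.53 ± 0.19), both higher before Na2EDTA than before CaEDTA, while the B cell list was lower at 4 h.

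Among the lists with no call in any comparison, gamma-delta T cell genes, with 3 on the array, had a median of -1.55 in both milk fever groups against healthy cows (adjusted p = 0.0716). Calciotropic hormone and vitamin D genes had a median of 1.07 from 0 h to 24 h of Na2EDTA (adjusted p = 0.112), and platelet genes 0.63 in group B against group H (adjusted p = 0.305). The lowest adjusted p over the comparisons was 0.0674 for apoptosis, 0.103 for fatty acid oxidation, 0.123 for plasma cell, 0.126 for erythroid, 0.202 for reference, 0.203 for metal response, 0.293 for eosinophil, basophil and mast cell and 0.32 for calcineurin and NFAT genes. Acute phase genes were tested in the 4 milk fever comparisons alone, with a lowest adjusted p of 0.473.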
